A study of Arabidopsis thaliana with 24 samples.

How the data were processed

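Messenger RNA from rosette leaves of Arabidopsis thaliana was sequenced in 24 libraries, which the labels place in 6 groups of 4 biological replicates: wild type (WT) and the grf6 grf8 double mutant, each at 0 h, 2 h and 4 h of dehydration. The plants were 24 days old, after 12 days on plates and 12 days on soil. The submitters' notes name fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1, RSEM, DESeq2 and edgeR together with the TAIR10 genome, without stating the role of each program or the version of all of them.

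Each deposited file lists 27664 genes with expected counts, which the authors had estimated per gene and rounded to whole numbers without scaling to library size. The same deposited files give FPKM (fragments per kilobase, scaled to mapped fragments) as the authors computed them, and these were read only to check them against the counts. Of the genes, 248 carry assembly names that start with MSTRG and 210 are encoded in organelles. Loci of the nuclear and organelle annotation were paired with a RefSeq gene table of build TAIR10.1, which held 26719 of them and lacked 697, and coordinates are from that table. Total counts per library ran from 17.4 to 22.4 M counts with a median of 18.5 M.

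The counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr on the 6 groups, which left 18841 genes, and libraries were scaled by the trimmed mean of M values (TMM), with factors from 0.843 to 1.28. One negative binomial model with a mean per group was fitted to all 24 libraries, and each comparison was tested with the edgeR quasi-likelihood test, two-sided. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change was derived from the quasi-likelihood statistic. Counts per M counts (CPM) use the TMM-scaled library totals. With 4 libraries against 4, an exact permutation test cannot give a two-sided p under 0.0286, so exact tests were kept for measures that combine several times.

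The 11 comparisons were 2 h against 0 h, 4 h against 0 h and 4 h against 2 h in each genotype, grf6 grf8 against WT at each of the 3 times, and the difference between genotypes of the 2 h and of the 4 h response, tested as interaction terms. The size of the response was compared between genotypes by an exact permutation test, two-sided, in which genotype labels were exchanged within 0 h and within the later time. Its genes were those called with an absolute log2 fold change of at least 1 in the response averaged over both genotypes, and its value was the median difference of response on log2 CPM, signed by the direction of the response.

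The comparisons, their tests, the rule for naming genes, 37 gene lists with 457 members and most of the alternatives were chosen before the data were examined. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between members, again with an estimated correlation, and with fry, adjusted over the 37 lists of a comparison. At the preset correlation camera also passed lists when libraries were regrouped so that no group difference remained, as described last. Its p-values alone therefore do not show a difference between groups. For each list the number of members that rose and fell was counted both over all genes tested and adjusted over the list alone. The cell cycle score of a library is the mean log2 CPM of the tested members of the cell cycle list.

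Genes are named by rule. All 13 members of the 14-3-3 family are given, GRF6 and GRF8 first. Each comparison gives up to the 6 highest and the 6 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 10 CPM in at least one group and groups that do not overlap, leaving out organelle genes. For 4 h against 2 h in each genotype, only some of the genes that meet this rule are named. For the 2 differences of response the gene had to be called and reach 10 CPM in at least one of the 4 groups. Each gene list that is described gives up to 4 tested members with the smallest adjusted p. Genes named outside this rule are said to be chosen after their values were seen.

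The alternatives were DESeq2 size factors (RLE) in edgeR, the DESeq2 1.42.0 Wald test, no low-count filter beyond 1 count, a stricter filter (over 1 CPM in at least 4 libraries and a mean of at least 5 CPM), the replicate number as a block, a fit of only the groups compared, a 2-fold minimum, and leaving out each library in turn. After the data were seen, a fit without the 5 libraries with a cell cycle score over 1 and a fit with that score as a covariate were added. The procedure was tested on simulated data, with 200 genes changed by known amounts in counts drawn to match these libraries. Between genotypes at 0 h it recovered 8.96% of genes changed 1.5-fold, 44.8% of those changed 2-fold and 83.3% of those changed 4-fold. For the differences of the 2 h and 4 h response, 13.4% and 25.4% of genes changed 2-fold and 71.2% and 72.7% of those changed 4-fold were recovered. The simulated counts carry no correlation between genes.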

Results

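Leaf mRNA was measured in 24 libraries of WT and grf6 grf8 plants taken before dehydration (0 h) and after 2 h and 4 h of dehydration, with 4 libraries per group. GRF6 and GRF8 encode 14-3-3 proteins, which bind phosphorylated partner proteins and change their activity, location or stability. Mean total counts per library, in M counts, were 19.4 ± 1.48, 18.9 ± 1.28 and 18.4 ± 0.976 (SD, n = 4) in WT at 0 h, 2 h and 4 h, and 18.8 ± 1.54, 20.7 ± 1.90 and 18.1 ± 0.291 in grf6 grf8. Libraries of a group correlated across genes with Spearman values between 0.904 and 0.991. The 6 groups include no watered plants taken at 2 h or 4 h, so dehydration and time of day changed together.

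The first principal component of log2 CPM held 52.8% of the variance and followed dehydration, and the second held 16.3%. In both genotypes libraries at 0 h lay apart from those at 2 h and 4 h. Genes of the cell cycle list, which serve DNA replication and division and are quiet in grown leaves, differed widely between libraries of the same group. Their mean log2 CPM was 2.29 in WT 4 h replicate 4, 2.42 and 2.07 in grf6 grf8 4 h replicates 1 and 2, 1.28 in grf6 grf8 0 h replicate 1 and 1.14 in WT 2 h replicate 4, while the highest of the other 19 libraries was 0.605. The common dispersion of all libraries was 0.108, a coefficient of variation of 32.9%, and 22.3% without those 5 libraries. The sample labels give no batch.

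**Figure D1:**
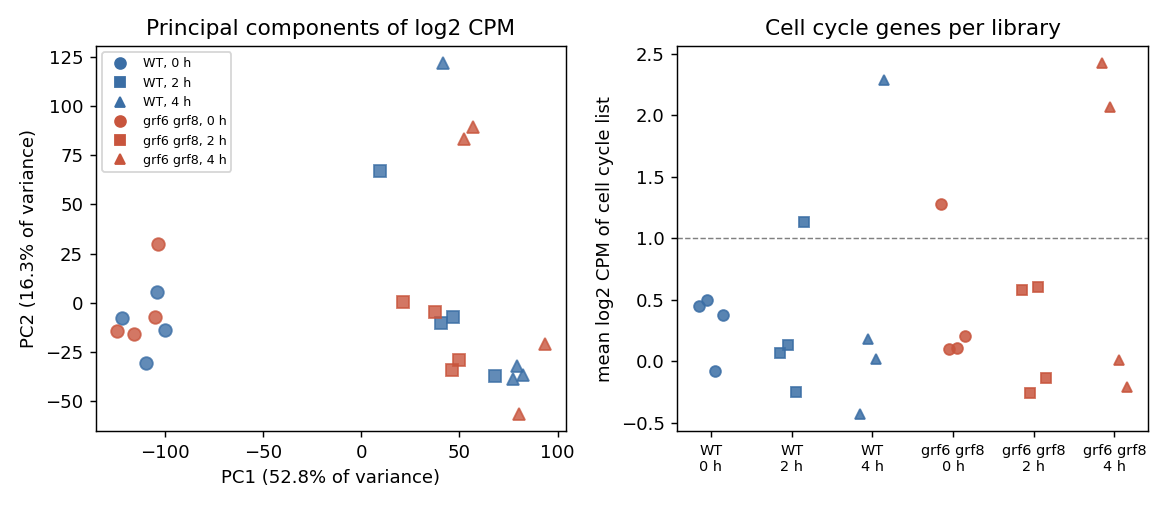
Left, each of the 24 libraries by its first and second principal component of log2 CPM, with genotypes by colour and times by symbol. Right, mean log2 CPM of the cell cycle list per library in the 6 groups, with the dashed line at 1 passed by 5 libraries from 1.14 to 2.42.

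The mutant was first examined for the transcripts of its mutated genes. GRF6 (AT5G10450, chromosome 5, 3283853 to 3286537, minus strand, TAIR10.1) was the most abundant 14-3-3 transcript in WT leaves, and in the mutant it was low but still measured. In WT it averaged 1573 ± 195, 734 ± 160.1 and 597 ± 203 CPM (SD, n = 4) at 0 h, 2 h and 4 h, and in grf6 grf8 307 ± 75.5, 77.7 ± 12.7 and 49.2 ± 9.81 CPM, which is 19.5%, 10.6% and 8.24% of WT. GRF8 (AT5G65430, chromosome 5, 26148150 to 26150593, minus strand) averaged 290.0 ± 43.0, 122 ± 18.0 and 106 ± 27.3 CPM in WT and 83.0 ± 6.50, 84.9 ± 4.18 and 57.3 ± 14.7 CPM in grf6 grf8, which is 28.6%, 69.8% and 53.9% of WT. GRF6 was lower in grf6 grf8 at 0 h (log2 fold change -2.36, SE 0.251, adjusted p = 2.5e-05), 2 h (-3.24, SE 0.261, adjusted p = 6.28e-07) and 4 h (-3.60, SE 0.265, adjusted p = 1.17e-07). GRF8 was lower at 0 h (log2 fold change -1.80, SE 0.185, adjusted p = 1.75e-05). At 2 h the difference of GRF8 was -0.52 and did not pass. For GRF8, grf6 grf8 against WT at 4 h gave a log2 fold change of -0.89 with an adjusted p of 0.173. It passed without WT 4 h replicate 4 (adjusted p = 0.00786) and without grf6 grf8 4 h replicate 4 (adjusted p = 0.0281), with the stricter filter (0.0361), with DESeq2 (0.0102) and with the cell cycle score as a covariate (-0.76, adjusted p = 0.0279), but not without the 5 libraries with high scores (0.331), in a range of 0.00786 to 1.00 over its alternatives.

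**Figure D2:**
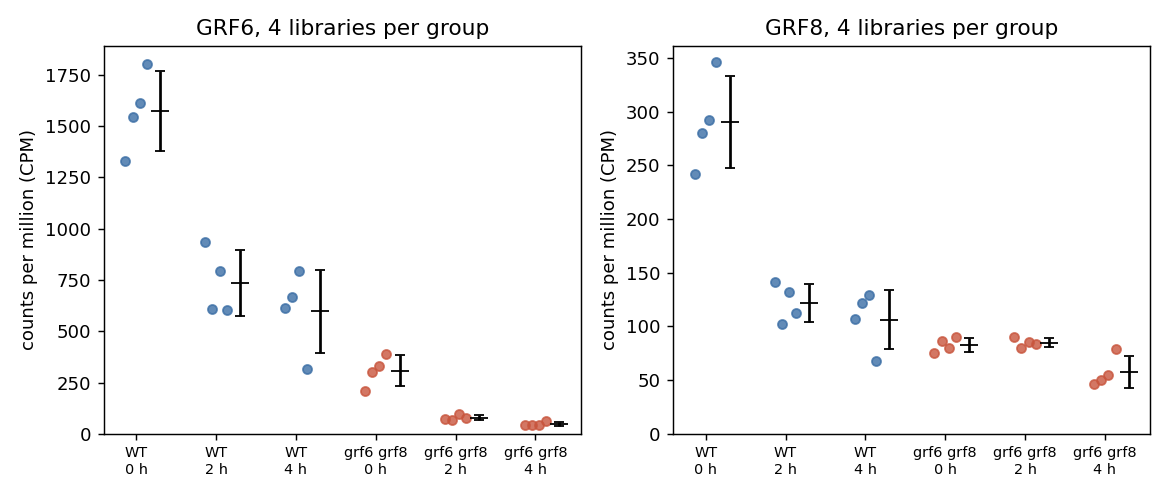
CPM of GRF6 (left) and GRF8 (right) in each library of the 6 groups, with the mean and SD of 4 libraries beside the points. GRF6 in grf6 grf8 lies between 43.7 and 388.1 CPM and in WT between 316.1 and 1803 CPM, while GRF8 of both genotypes comes close at 2 h and 4 h.

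In WT the transcripts of both genes were lower at 4 h than at 0 h, and other 14-3-3 members were higher or lower. At 4 h in WT, GRF6 had fallen (log2 fold change -1.40, SE 0.243, adjusted p = 7.25e-05), as had GRF8 (-1.45, SE 0.183, adjusted p = 1.68e-06), GRF9 (-0.83, SE 0.160, adjusted p = 0.000213) and GRF11 (-2.03, SE 0.390, adjusted p = 0.000198), while GRF3 (1.06, SE 0.136, adjusted p = 2.03e-06), GRF5 (0.88, SE 0.121, adjusted p = 4.97e-06), GRF2, GRF4, GRF7 and GRF10 had risen. GRF10 was not called without WT 0 h replicate 4 (adjusted p = 0.0538) or WT 4 h replicate 4 (0.0730). GRF1 did not pass at 4 h in WT. In WT at 0 h, 2 h and 4 h the means were 259 ± 29.5, 311 ± 36.7 and 268 ± 42.4 CPM (SD, n = 4) for GRF1. For GRF2 they were 67.0 ± 4.24, 84.1 ± 11.3 and 92.9 ± 14.3. For GRF3 they were 106 ± 5.63, 280.1 ± 66.4 and 221 ± 28.0. For GRF4 they were 70.8 ± 3.60, 109 ± 3.67 and 96.4 ± 4.42. They were 70.9 ± 7.15, 113 ± 13.4 and 130.1 ± 17.9 CPM for GRF5. For GRF7 they were 61.4 ± 11.5, 108 ± 32.8 and 99.96 ± 8.59. For GRF9 they were 249.6 ± 25.2, 150.2 ± 13.9 and 140.4 ± 32.1. For GRF10 they were 132 ± 10.96, 179 ± 11.1 and 173 ± 30.6. For GRF11 they were 44.7 ± 4.39, 10.13 ± 2.76 and 10.97 ± 5.06. GRF12 reached at most 1 count in a library and GRF13 is listed at 0 in every library, so neither was tested.

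In grf6 grf8 the means at 0 h, 2 h and 4 h were 311 ± 53.8, 397 ± 35.3 and 328 ± 39.3 CPM (SD, n = 4) for GRF1. For GRF2 they were 84.7 ± 8.62, 109 ± 7.97 and 124 ± 20.8. For GRF3 they were 131 ± 6.60, 381 ± 12.997 and 284 ± 15.6. For GRF4 they were 83.1 ± 6.85, 126 ± 11.8 and 113 ± 12.9. They were 106 ± 4.53, 166 ± 13.4 and 205 ± 22.8 CPM for GRF5, which is 149.8%, 147% and 158% of WT, and 345 ± 50.8, 266 ± 14.7 and 219 ± 39.2 CPM for GRF9, which is 138%, 177% and 156% of WT. GRF7 averaged 69.8 ± 5.44, 153 ± 51.4 and 121 ± 16.0 CPM, GRF10 147 ± 19.05, 203 ± 14.2 and 186 ± 12.9, and GRF11 45.4 ± 12.9, 13.3 ± 3.52 and 7.81 ± 4.71. None of these 9 members passed between genotypes at a single time in the edgeR test, but GRF5 and GRF9 passed in some alternatives. For GRF5, grf6 grf8 against WT at 0 h had an adjusted p of 0.0135 with the stricter filter, 0.00604 with DESeq2, 0.00391 with the cell cycle score as a covariate and 0.0477 without the 5 libraries with high scores, in a range up to 1.00. For GRF5, grf6 grf8 against WT at 2 h had 0.0108 with DESeq2 and 0.0106 with the covariate, in a range up to 1.00. At the last time, GRF5, grf6 grf8 against WT at 4 h, had 0.00589 with the stricter filter, 0.000574 with DESeq2, 0.0481 without grf6 grf8 4 h replicate 2 and 0.000493 with the covariate, in a range up to 1.00. For GRF9, grf6 grf8 against WT at 2 h had 0.0359 with the stricter filter, 0.00268 with DESeq2, 0.00160 with the covariate and 0.0133 without the 5 libraries, in a range up to 0.641. Last, GRF9, grf6 grf8 against WT at 4 h, had 0.00397 with the covariate, in a range up to 1.00.

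WT at 2 h against 0 h asked what the first hours of dehydration did to leaves with intact GRF6 and GRF8. Genes of the abscisic acid (ABA) response rose together: the phosphatases that hold back ABA signalling, the proteins that protect drying cells and the transcription factors that switch both on. Genes for cuticular wax and jasmonate, a hormone of wounding and defence, rose too, and genes of photosynthesis fell. Of 18841 genes, 4346 rose and 3617 fell. The largest rises by the naming rule were in LEA7 (AT1G52690), a late embryogenesis abundant protein gene that averaged 0.0136 CPM at 0 h and 44.4 CPM at 2 h, in AT1G69480 (log2 fold change 8.09, SE 0.473, adjusted p = 1.29e-10), in LEA4-5 (AT5G06760, 8.04, SE 0.574, adjusted p = 1.53e-09) and in the kinase gene MAPKKK18 (AT1G05100, 7.74, SE 0.523, adjusted p = 7.96e-10), followed by AT1G10585 (7.61, SE 0.782, adjusted p = 1.86e-07) and AAE12 (AT1G65890, 7.499, SE 0.833, adjusted p = 4.9e-07). The largest falls were in the wall-loosening gene XTH25 (AT5G57550, log2 fold change -5.02, SE 0.663, adjusted p = 4.27e-06), AT4G12980 (-4.88, SE 0.425, adjusted p = 2.23e-08), the growth genes GASA6 (AT1G74670, -4.57, SE 0.504, adjusted p = 4.52e-07) and PRE1 (AT5G39860, -4.44, SE 0.406, adjusted p = 4.26e-08), EXL3 (AT5G51550, -4.54, SE 0.857, adjusted p = 0.000232) and the arabinogalactan gene FLA9 (AT1G03870, -4.49, SE 0.556, adjusted p = 1.94e-06).

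Of the lists fixed beforehand, the clade A PP2C phosphatases had 8 of 8 tested members risen (median 3.93, adjusted p = 1.1e-09). Members included ABI2 (AT5G57050, log2 fold change 4.44, SE 0.213, adjusted p = 1.25e-11) and HAI1 (AT5G59220, 6.86, SE 0.506, adjusted p = 2.41e-09). The dehydration effector genes had 18 of 18 risen (median 2.97, adjusted p = 4.25e-13), with RD20 (AT2G33380, log2 fold change 6.06, SE 0.347, adjusted p = 9.73e-11) and KIN1 (AT5G15960, 5.13, SE 0.499, adjusted p = 9.68e-08). The drought transcription factors had 14 of 15 risen (median 2.51, adjusted p = 4.75e-09), with HB7 (AT2G46680, log2 fold change 3.69, SE 0.253, adjusted p = 9.43e-10) and ANAC019 (AT1G52890, 5.02, SE 0.378, adjusted p = 3.19e-09). The ABF/ABI factors had 3 risen and 1 fallen of 5 (median 2.497, adjusted p = 0.0411), with ABF2 risen (AT1G45249, log2 fold change 3.32, SE 0.237, adjusted p = 1.53e-09). The genes of raffinose and galactinol, sugars that protect drying cells, had 4 of 4 risen (median 2.28, adjusted p = 0.00201), with RS5 (AT5G40390, log2 fold change 2.79, SE 0.234, adjusted p = 1.44e-08). ABA catabolism had 5 of 5 risen (median 1.58, adjusted p = 0.0216). Counts adjusted over the list alone were equal to these for all 6 lists. With an estimated correlation the adjusted p of the 10 lists passing in this comparison was 0.149 to 0.746. No list passed camera in any of the 11 comparisons with an estimated correlation.

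Cuticular wax and cutin had 16 of 17 risen in WT at 2 h, and 17 adjusted over the list alone (median 2.81, adjusted p = 1.16e-11), with CER2 (AT4G24510, log2 fold change 3.66, SE 0.326, adjusted p = 3.15e-08). Jasmonate synthesis and response had 20 risen and 1 fallen of 25, and 22 and 1 adjusted over the list alone (median 2.399, adjusted p = 4.04e-08), with JAZ1 (AT1G19180, log2 fold change 3.59, SE 0.381, adjusted p = 2.69e-07) and AOC2 (AT3G25770, 3.28, SE 0.430, adjusted p = 3.95e-06). Aquaporins, the water channels of plasma membrane and vacuole, had 12 risen and 3 fallen of 17, and 13 and 3 adjusted over the list alone (median 2.49, adjusted p = 0.000118), with PIP1;4 (AT4G00430, log2 fold change 5.87, SE 0.336, adjusted p = 9.73e-11) and TIP1;1 (AT2G36830, 4.59, SE 0.365, adjusted p = 7.14e-09). Nuclear photosynthesis genes had 28 of 50 fallen and 0 risen, and 31 fallen adjusted over the list alone (median -0.94, adjusted p = 7.49e-08), with PRK (AT1G32060, log2 fold change -1.81, SE 0.309, adjusted p = 8.04e-05) and LHCB4.2 (AT3G08940, -1.86, SE 0.328, adjusted p = 0.000119).

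The other 27 lists did not pass camera in WT at 2 h. ABA biosynthesis had 4 risen and 2 fallen of 7, with NCED3 risen (AT3G14440, log2 fold change 2.19, SE 0.280, adjusted p = 2.81e-06), ABA receptors 2 and 2 of 8, SnRK2 kinases 1 and 2 of 10, CBF/DREB1 factors 2 and 2 of 5, and proline metabolism 2 and 1 of 6, with P5CS1 risen (AT2G39800, 2.66, SE 0.424, adjusted p = 4.04e-05) and PRODH1 fallen (AT3G30775, -3.72, SE 0.547, adjusted p = 1.58e-05). Senescence and chlorophyll breakdown had 10 risen and 1 fallen of 14, ethylene biosynthesis 4 and 1 of 9, salicylate 5 and 0 of 23, brassinosteroid biosynthesis 1 and 3 of 7, antioxidant enzymes 3 and 1 of 14, and plasma membrane H+-ATPases 3 and 2 of 9. The morning-phased clock genes had 4 risen and 6 fallen of 12, with RVE7 fallen (AT1G18330, log2 fold change -2.77, SE 0.283, adjusted p = 1.72e-07), and the evening-phased ones 1 and 4 of 9. The counts were 5 and 4 of 11 for the 14-3-3 family, 1 and 1 of 5 for nitrate assimilation, 3 and 0 of 10 for heat shock proteins, 1 and 2 of 10 for alpha-expansins, 1 and 1 of 10 for Aux/IAA genes, 5 and 0 of 11 for flavonoid synthesis and 8 and 1 of 13 for aliphatic glucosinolate synthesis. Markers of cell types and states gave 0 and 0 of 11 for the cell cycle, 3 and 1 of 11 for guard cells, 1 and 0 of 2 for stomatal development, 1 and 2 of 9 for the vasculature, 0 and 0 of 3 for epidermis and trichomes, 0 and 0 of 1 for roots and 1 and 0 of 6 for floral organs. Adjusted over the list alone, the 14-3-3 family had 6 and 4, proline metabolism 2 and 2, the evening clock 1 and 5, glucosinolate synthesis 8 and 2 and floral organs 0 and 0, and the others were as given. At an unadjusted p under 0.05, edgeR gave 9430 genes where chance alone gives 942.1.

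**Figure D3:**
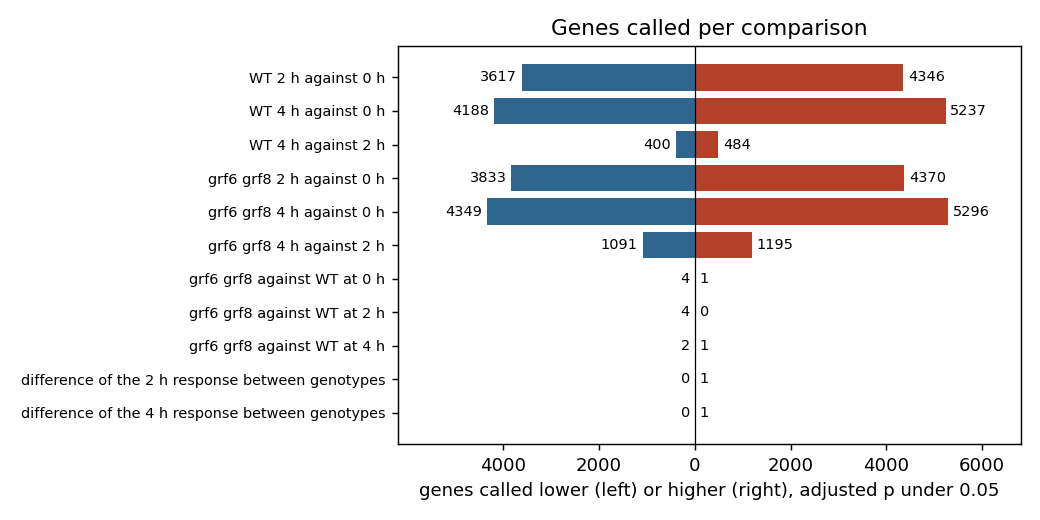
Number of genes called lower (left bars) and higher (right bars) at an adjusted p under 0.05 in each of the 11 comparisons. The dehydration comparisons against 0 h reach 4188 to 5296 genes at 4 h, and the comparisons between genotypes at most 4 genes in a direction.

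WT at 4 h against 0 h asked how the response looked after longer drying. Genes of protective proteins and chlorophyll breakdown rose, and genes of photosynthesis fell. In all, 5237 genes rose and 4188 fell. By the naming rule the largest rises were in LEA7, which averaged 294.4 CPM at 4 h, in AT3G02480 (log2 fold change 11.24, SE 0.802, adjusted p = 8.53e-10), and in genes with no or nearly no counts at 0 h, AT2G42560 (70.8 CPM at 4 h), LEA18 (AT2G35300, 48.8 CPM), PAO2 (AT2G43020, 47.2 CPM) and AT2G02700 (11.5 CPM). The largest falls were in AT1G15125 (log2 fold change -6.02, SE 1.07, adjusted p = 9.27e-05), MSTRG.238 (-5.88, SE 0.292, adjusted p = 1.03e-11), AACT1 (AT5G61160, -5.82, SE 0.960, adjusted p = 3.95e-05), AT5G02760 (-5.66, SE 1.13, adjusted p = 0.000290), PAR1 (AT2G42870, -5.63, SE 1.05, adjusted p = 0.000148) and AT1G78450 (-5.41, SE 0.455, adjusted p = 7.08e-09).

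At 4 h in WT, the PP2C phosphatases had 8 of 8 risen (median 4.55, adjusted p = 6.2e-10), with HAB1 (AT1G72770, log2 fold change 3.92, SE 0.295, adjusted p = 1.87e-09). The drought factors had 15 of 15 risen (median 3.04, adjusted p = 6.2e-10), with HB12 (AT3G61890, log2 fold change 3.04, SE 0.251, adjusted p = 5.73e-09). The dehydration effectors had 17 of 18 risen (median 3.07, adjusted p = 4.42e-12), with RD20 (log2 fold change 6.74, SE 0.358, adjusted p = 1.59e-11) and TSPO (AT2G47770, 7.30, SE 0.578, adjusted p = 3.46e-09). Wax and cutin had 17 of 17 risen (median 2.000, adjusted p = 1.41e-08), with WSD1 (AT5G37300, log2 fold change 4.42, SE 0.519, adjusted p = 6.55e-07). Aquaporins had 12 risen and 3 fallen of 17 (median 2.39, adjusted p = 0.000240) and raffinose synthesis 3 of 4 risen (median 2.42, adjusted p = 0.0179). The ABF/ABI factors had 3 risen and 1 fallen of 5 (median 3.48, adjusted p = 0.0498), with ABF3 (AT4G34000, log2 fold change 3.48, SE 0.282, adjusted p = 4.52e-09) and ABI5 (AT2G36270, 4.06, SE 0.449, adjusted p = 2.95e-07). Jasmonate genes had 21 risen and 1 fallen of 25 (median 2.01, adjusted p = 2.64e-06), with VSP2 (AT5G24770, log2 fold change 4.59, SE 0.582, adjusted p = 1.72e-06). Senescence and chlorophyll breakdown had 10 risen and 1 fallen of 14 (median 2.15, adjusted p = 0.0206), with SGR1 (AT4G22920, log2 fold change 3.58, SE 0.392, adjusted p = 2.52e-07) and NAP (AT1G69490, 2.68, SE 0.345, adjusted p = 2.01e-06). Photosynthesis genes had 37 of 50 fallen (median -1.21, adjusted p = 6.2e-10), with LHCB3 (AT5G54270, log2 fold change -2.29, SE 0.348, adjusted p = 1.6e-05). Adjusted over the list alone, 4 rose and 1 fell of the ABF/ABI factors, 22 and 1 of the jasmonate genes and 10 and 2 of the senescence genes, 38 photosynthesis genes fell, and the counts of the other 6 lists were equal. Their adjusted p with an estimated correlation was 0.208 to 0.644. Outside these lists P5CS1 rose (log2 fold change 4.09, SE 0.452, adjusted p = 2.95e-07), PRODH1 fell (-2.71, SE 0.522, adjusted p = 0.000206) and the brassinosteroid genes DET2 (AT2G38050, -1.69, SE 0.172, adjusted p = 1.04e-07) and CPD (AT5G05690, -1.48, SE 0.263, adjusted p = 9.02e-05) fell.

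WT at 4 h against 2 h asked what still changed in the second part of the drying. Some genes of late embryogenesis abundant (LEA) proteins, which protect drying cells, were among the largest rises by the naming rule, and few members of the PP2C phosphatases and drought factors were called. In the edgeR test 484 genes rose and 400 fell, and DESeq2 called 1647. This count moved with single libraries, to 423 without WT 2 h replicate 2, 388 without WT 4 h replicate 1, 543 without WT 4 h replicate 2, 538 without WT 4 h replicate 3 and 3455 without WT 4 h replicate 4, and it was 37 in a fit of only the 2 groups, 4010 without the 5 libraries with high cell cycle scores and 3854 with the score as a covariate. Other groupings of the same libraries into 4 and 4 called up to 5592 genes, so chance is not excluded for this count. The groupings with 5592 and 2010 genes put WT 2 h replicate 4 and WT 4 h replicate 4 on the same side. Both libraries have high cell cycle scores, but not all groupings that did so called many genes. Among the largest rises were AT3G17520 (log2 fold change 5.81, SE 0.474, adjusted p = 7.96e-07), LEA18 (3.68, SE 0.444, adjusted p = 0.000190) and the lipid transfer protein gene LTP4 (AT5G59310, 3.42, SE 0.440, adjusted p = 0.000190), and the chlorophyllase gene CLH1 was among the largest falls (AT1G19670, -2.53, SE 0.480, adjusted p = 0.00406). The dehydration effectors had 5 of 18 risen (median 0.36, adjusted p = 0.00287), with LEA7 (log2 fold change 2.73, SE 0.345, adjusted p = 0.000170) and RAB18 (AT5G66400, 2.47, SE 0.416, adjusted p = 0.00195). The PP2C phosphatases had 2 of 8 risen and 6 adjusted over the list alone (median 0.69, adjusted p = 0.000124). The drought factors had 2 of 15 risen and 5 adjusted over the list alone (median 0.52, adjusted p = 0.000255). Proline metabolism had 2 of 6 risen (median 0.61, adjusted p = 0.0152), with an adjusted p of 0.0976 when the 5 libraries with high cell cycle scores were left out. The evening clock genes passed with no member called and 2 risen adjusted over the list alone (median 0.42, adjusted p = 0.0152). Photosynthesis genes passed with no member called (median -0.31, adjusted p = 0.000255). Without those 5 libraries their adjusted p was 0.530. The 6 lists had, with an estimated correlation, an adjusted p of 0.453 to 0.987.

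In grf6 grf8, 2 h against 0 h asked whether the early response runs in the mutant, where GRF6 was called lower at both times and GRF8 at 0 h. The ABA-responsive phosphatases, protective proteins and drought factors rose here as well, with wax, raffinose and jasmonate genes, and photosynthesis genes fell. Heat shock protein genes, which hold proteins in shape under stress, and salicylate genes of pathogen defence also passed as lists. In all, 4370 genes rose and 3833 fell. By the naming rule the largest rises were in AT4G33905 (log2 fold change 9.03, SE 0.755, adjusted p = 1.52e-08), LEA7 (8.51, SE 0.514, adjusted p = 2.41e-10), AT5G50360 (8.19, SE 0.540, adjusted p = 6.25e-10), the jasmonate-inactivating gene CYP94B3 (AT3G48520, 8.10, SE 0.821, adjusted p = 1.59e-07), AT2G43580 (7.79, SE 0.486, adjusted p = 3.33e-10) and MAPKKK18 (7.72, SE 0.518, adjusted p = 7.27e-10). The largest falls were in BZIP61 (AT3G58120, log2 fold change -7.87, SE 1.56, adjusted p = 0.000385), AT1G19530 (-7.10, SE 0.989, adjusted p = 1.73e-05), AT3G54830 (-6.11, SE 0.588, adjusted p = 8.51e-08), FLA9 (-6.06, SE 0.610, adjusted p = 1.47e-07), AT1G50040 (-5.63, SE 0.569, adjusted p = 1.57e-07) and AACT1 (-5.62, SE 0.939, adjusted p = 6.77e-05).

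In the mutant at 2 h, PP2C phosphatases had 8 of 8 risen (median 3.69, adjusted p = 3.66e-09), with ABI2 (log2 fold change 4.09, SE 0.209, adjusted p = 2.97e-11). The effectors had 18 of 18 risen (median 3.03, adjusted p = 3.87e-13), with RD20 (log2 fold change 6.02, SE 0.346, adjusted p = 1.55e-10). The drought factors had 13 of 15 risen (median 2.197, adjusted p = 5.63e-09), with ANAC019 (log2 fold change 5.08, SE 0.379, adjusted p = 2.94e-09). The ABF/ABI factors had 4 of 5 risen (median 2.14, adjusted p = 0.00396), raffinose synthesis 4 of 4 (median 2.24, adjusted p = 0.00343), wax and cutin 16 of 17 (median 2.44, adjusted p = 1.9e-10), with KCS2 (AT1G04220, log2 fold change 7.23, SE 0.645, adjusted p = 3.16e-08). Jasmonate genes had 18 risen and 1 fallen of 25 (median 2.08, adjusted p = 5.02e-07), with AOC2 (log2 fold change 4.26, SE 0.451, adjusted p = 2.65e-07). Aquaporins had 11 risen and 3 fallen of 17 (median 1.92, adjusted p = 0.00808), with PIP1;4 risen (log2 fold change 5.61, SE 0.332, adjusted p = 1.85e-10) and PIP1;5 fallen (AT4G23400, -3.59, SE 0.339, adjusted p = 6.84e-08). Photosynthesis genes had 19 of 50 fallen (median -0.69, adjusted p = 6.7e-05). Salicylate genes had 10 of 23 risen (median 1.06, adjusted p = 0.0371), with SARD4 (AT5G52810, log2 fold change 1.51, SE 0.302, adjusted p = 0.000421). The list no longer passed with the cell cycle score as a covariate (adjusted p = 0.0618). Heat shock proteins had 6 of 10 risen (median 3.08, adjusted p = 0.0179), with HSP70-4 (AT3G12580, log2 fold change 3.41, SE 0.609, adjusted p = 0.000135). Adjusted over the list alone, 14 drought factors and 7 heat shock protein genes rose, and the counts of the other 9 lists were equal. With an estimated correlation the adjusted p of the lists was 0.147 to 0.811.

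In grf6 grf8, 4 h against 0 h gave the longer response of the mutant. Protective proteins and ABA response genes rose, ABA synthesis genes passed as a list, and photosynthesis and brassinosteroid synthesis genes fell. In all, 5296 genes rose and 4349 fell. By the naming rule the largest rises were in AT3G02480 (log2 fold change 11.67, SE 0.802, adjusted p = 5.11e-10), LEA7 (11.27, SE 0.546, adjusted p = 7.35e-12) and AT5G50360 (10.78, SE 0.564, adjusted p = 1.29e-11), and in genes with no or nearly no counts at 0 h, AT2G42560 (100.8 CPM at 4 h), the heat shock factor gene HSFA6B (AT3G22830, 48.1 CPM) and AT2G02700 (20.9 CPM). AT1G19530 went from 12.7 CPM at 0 h to a listed 0 in all 4 libraries at 4 h. Other large falls were in AT3G54830 (log2 fold change -6.76, SE 0.623, adjusted p = 2.51e-08), AACT1 (-6.18, SE 0.988, adjusted p = 2.54e-05), XTH25 (-5.98, SE 0.688, adjusted p = 4.44e-07), MSTRG.238 (-5.97, SE 0.292, adjusted p = 7.37e-12) and AT5G02760 (-5.69, SE 1.103, adjusted p = 0.000211).

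In the mutant at 4 h, PP2C phosphatases had 8 of 8 risen (median 4.12, adjusted p = 7.85e-09), with HAI1 (log2 fold change 7.38, SE 0.517, adjusted p = 6.76e-10). The effectors had 18 of 18 risen (median 3.23, adjusted p = 1.29e-11), with RD20 (log2 fold change 6.79, SE 0.359, adjusted p = 1.43e-11). The drought factors had 14 of 15 risen (median 2.62, adjusted p = 4.11e-09), with HB7 (log2 fold change 4.04, SE 0.257, adjusted p = 1.91e-10). Wax and cutin had 17 of 17 risen (median 2.14, adjusted p = 5.67e-08). The ABF/ABI factors had 4 risen and 1 fallen of 5 (median 3.26, adjusted p = 0.0367), ABA biosynthesis 5 of 7 risen (median 1.77, adjusted p = 0.0367), with ABA3 (AT1G16540, log2 fold change 1.83, SE 0.237, adjusted p = 1.99e-06) and NCED3 (1.77, SE 0.276, adjusted p = 1.87e-05). Aquaporins had 11 risen and 3 fallen of 17 (median 1.76, adjusted p = 0.0259), and jasmonate genes 18 risen and 1 fallen of 25 (median 2.19, adjusted p = 1.02e-06). Photosynthesis had 36 of 50 fallen (median -1.14, adjusted p = 1.6e-07), with LHCB4.2 (log2 fold change -2.80, SE 0.340, adjusted p = 8.71e-07). When adjusted over the list alone, 12 aquaporins rose, 37 photosynthesis genes fell and 9 flavonoid genes rose, and the counts of the other 11 lists were equal. The 14 lists had an adjusted p with an estimated correlation of 0.207 to 0.732. The other 5 lists lost their call when the 5 libraries with high cell cycle scores were left out. Raffinose synthesis had 3 of 4 risen (median 2.18, adjusted p = 0.0259, 0.0687 without them) and ABA catabolism 4 of 5 risen (median 2.04, adjusted p = 0.0399, 0.0984 without them). Brassinosteroid synthesis had 1 risen and 5 fallen of 7 (median -1.40, adjusted p = 0.0399, 0.0687 without them), heat shock proteins 8 of 10 risen (median 3.17, adjusted p = 0.0259, 0.118 without them) and flavonoid synthesis 8 of 11 risen (median 4.55, adjusted p = 0.0367, 0.723 without them). With the score as a covariate ABA catabolism (0.0695), heat shock proteins (0.0714) and flavonoid synthesis (0.116) did not pass either. The fit without the 5 libraries lacks grf6 grf8 0 h replicate 1 and grf6 grf8 4 h replicates 1 and 2. A lost call can therefore reflect fewer libraries.

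**Figure D4:**
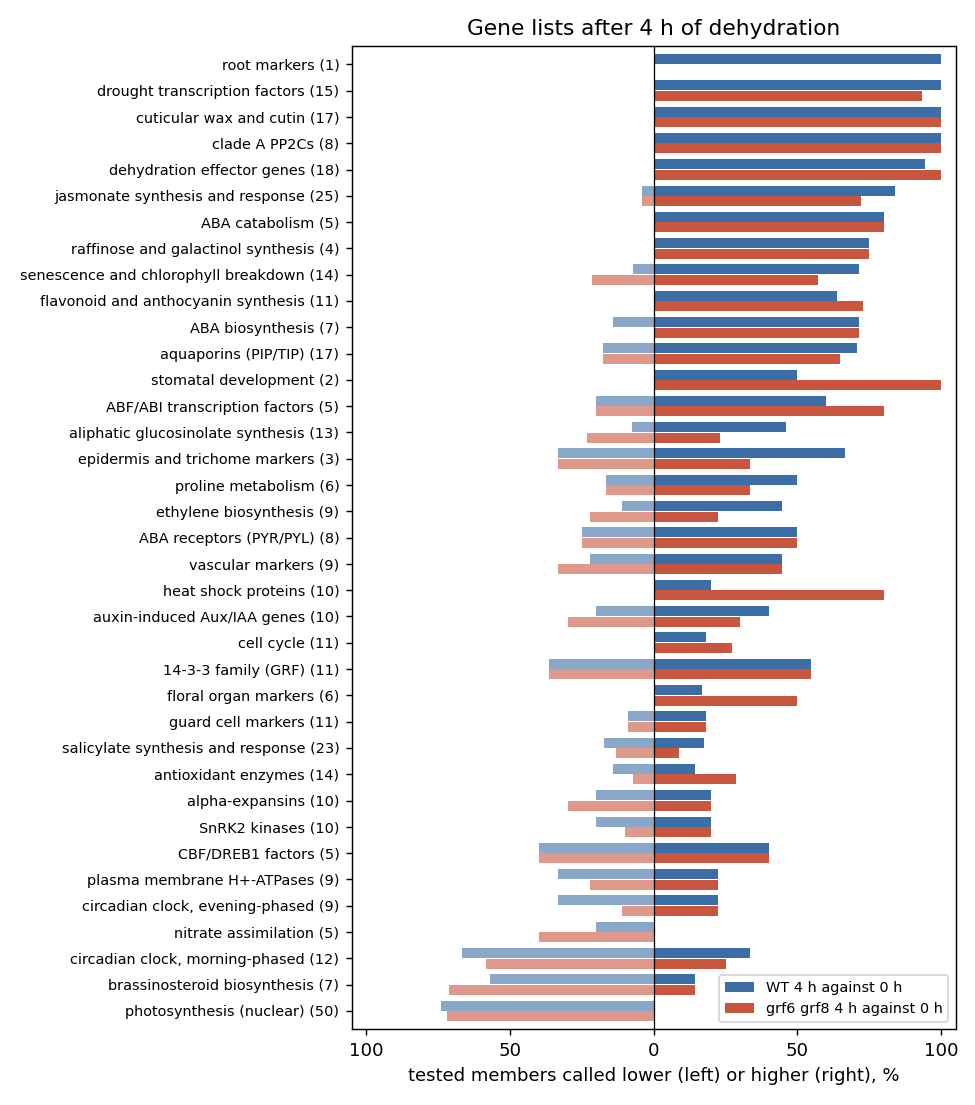
Share of tested members, in %, called lower (left bars) or higher (right bars) after 4 h against 0 h in WT (blue) and grf6 grf8 (red), for each of the 37 lists with the number of tested members in brackets. PP2C phosphatases reach 8 of 8 risen in both genotypes, and photosynthesis genes 37 and 36 of 50 fallen.

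In grf6 grf8, 4 h against 2 h asked what changed late in the mutant. Single members of the effectors and drought factors rose, and a gene of a receptor-like kinase and a gene of a receptor-like protein were among the largest falls. In the edgeR test 1195 genes rose and 1091 fell, and the count was 1318, 1471 and 1362 without grf6 grf8 2 h replicates 1, 2 and 4, 1312 in a fit of only the 2 groups, 5861 without the 5 libraries with high cell cycle scores and 6099 with the score as a covariate. Among the largest rises were AT3G17520 (log2 fold change 5.59, SE 0.448, adjusted p = 5.64e-07), AT3G53040 (4.41, SE 0.516, adjusted p = 3.79e-05), AT3G02480 (4.39, SE 0.525, adjusted p = 4.5e-05) and AT3G27025 (3.78, SE 0.525, adjusted p = 0.000127). CRK6 (AT4G23140, log2 fold change -3.06, SE 0.664, adjusted p = 0.00509), MSRB9 (AT4G21850, -3.05, SE 0.774, adjusted p = 0.0140), RLP23 (AT2G32680, -2.76, SE 0.660, adjusted p = 0.00985) and AT5G08760 (-2.51, SE 0.308, adjusted p = 4.61e-05) were among the largest falls, and CIB1 (AT4G34530) fell from 11.8 CPM at 2 h to a listed 0 in all 4 libraries at 4 h (adjusted p = 0.0191). The effectors had 5 of 18 risen and 7 adjusted over the list alone (median 0.32, adjusted p = 0.0145), with RAB18 (log2 fold change 2.77, SE 0.421, adjusted p = 0.000303). The drought factors had 5 of 15 risen and 7 adjusted over the list alone (median 0.82, adjusted p = 0.0110), with HSFA6B (log2 fold change 2.39, SE 0.449, adjusted p = 0.00192). The PP2C phosphatases had 2 of 8 risen by either adjustment (median 0.42, adjusted p = 0.0389). The evening clock genes had 2 of 9 risen and 3 adjusted over the list alone (median 0.40, adjusted p = 0.0389). Photosynthesis had 4 of 50 fallen and 0 adjusted over the list alone (median -0.41, adjusted p = 0.00178), salicylate 4 of 23 fallen and 5 adjusted over the list alone (median -0.72, adjusted p = 0.0256) and flavonoid synthesis 4 of 11 risen and 9 adjusted over the list alone (median 2.83, adjusted p = 0.00894). Without the 5 libraries with high cell cycle scores these last 3 lists had adjusted p-values of 0.227, 0.239 and 0.614, and with the covariate 0.487, 0.141 and 0.192. All 7 lists had an adjusted p of 0.962 with an estimated correlation.

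The 2 genotypes were then set side by side. Most genes that rose or fell after 2 h or 4 h of dehydration in WT did so in the mutant too, among them many ABA response, protective protein and wax genes. At 2 h, 3559 genes rose in both genotypes where independent lists would share 1008, and 2960 fell in both where 735.8 would be shared, with 2 genes called in opposite directions. At 4 h, 4574 rose in both (1472 if independent), 3599 fell in both (966.7 if independent) and 0 were called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes of the genotypes correlated with r = 0.874 (rho = 0.878) at 2 h and r = 0.928 (rho = 0.924) at 4 h. The median response of 4929 genes at 2 h was 1.58 in WT and 1.63 in grf6 grf8 on the log2 scale, and the median difference of 0.0256 lay within the range of -0.318 to 0.318 that holds 95% of 4900 exchanges of genotype labels (exact permutation p = 0.884). Its sign turned without WT 0 h replicate 1 (-0.00846), WT 2 h replicate 4 (-0.102), grf6 grf8 0 h replicate 4 (-0.00190) or grf6 grf8 2 h replicate 4 (-0.0111). For 5968 genes at 4 h the medians were 1.63 and 1.70 and the difference 0.0569 (exact permutation p = 0.660, range -0.252 to 0.252), and -0.0974 without WT 4 h replicate 4. Without the 5 libraries with high cell cycle scores, a choice made after seeing the data, the difference at 4 h was 0.150 with an exact permutation p of 0.0400. That test lacks grf6 grf8 0 h replicate 1, WT 4 h replicate 4 and grf6 grf8 4 h replicates 1 and 2. It rests on 350 exchanges of labels. A simulated response that was larger in the mutant by 0.378 and 0.406 gave exact permutation p-values of 0.0159 at 2 h and 0.00286 at 4 h. The simulated counts carry no correlation between genes, so these values do not give the sensitivity of the test on the real libraries.

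**Figure D5:**
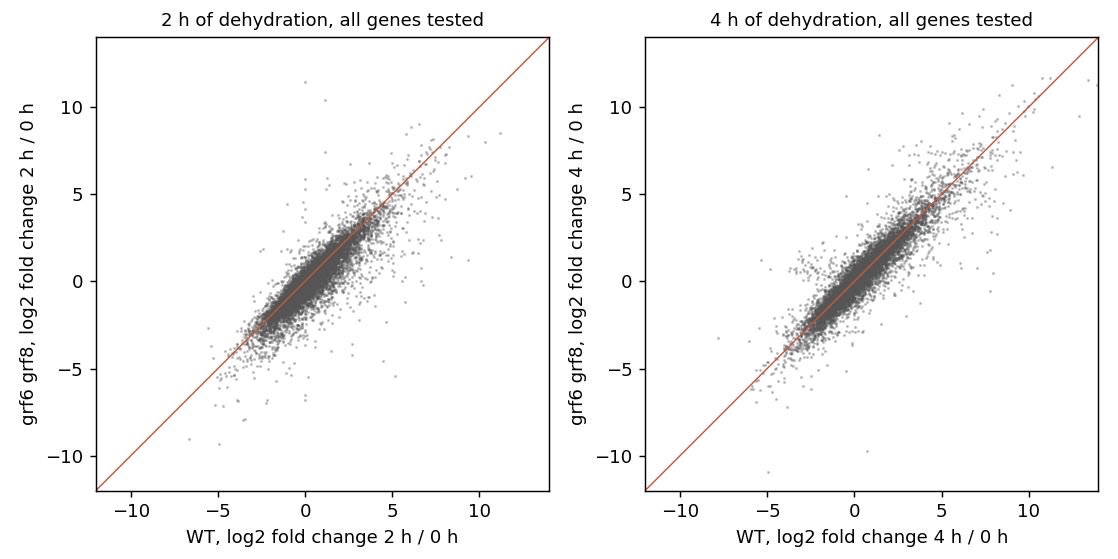
Log2 fold change of each of 18841 genes after 2 h (left) and 4 h (right) against 0 h, in WT (horizontal) and grf6 grf8 (vertical), with the line of equal response in red. The points follow the line with r = 0.874 at 2 h and r = 0.928 at 4 h.

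Genotypes at 0 h were compared to ask what the mutations changed in leaves before drying. Apart from the mutated genes, hardly any gene was called, and no drought or ABA gene was among those called. The edgeR test called 5 genes, 1 higher and 4 lower in grf6 grf8, with 547 genes at an unadjusted p under 0.05 where chance alone gives 942.1, and DESeq2 called 14. A fit without the 5 libraries with high cell cycle scores called 12 genes, with 1562 at an unadjusted p under 0.05, and the fit with the score as a covariate called 8, with 1030. With all 24 libraries and no covariate, the lower genes besides GRF6 and GRF8 were MSTRG.13239 (log2 fold change -6.88, SE 0.554, adjusted p = 3.23e-07), an assembled transcript with 11.6 CPM in WT and nearly none in grf6 grf8, and AT5G07810, a protein-coding locus on chromosome 5 with 3.44 CPM in WT and 0.333 CPM in grf6 grf8 (-3.34, SE 0.261, adjusted p = 3.23e-07), which is named after its values were seen. For AT1G55170, grf6 grf8 against WT at 0 h gave a higher level (log2 fold change 0.82, SE 0.125, adjusted p = 0.00555). The gene was not called in a fit of the 0 h groups alone (adjusted p = 0.107, range over alternatives 4.63e-09 to 0.107). Camera passed 7 lists without a called member, the aquaporins higher (median 0.42, adjusted p = 3.98e-09), the PP2C phosphatases higher (median 0.26, adjusted p = 0.0125) and the effectors higher (median 0.13, adjusted p = 0.0258), and the morning clock (median -0.13, adjusted p = 0.00265), heat shock proteins (median -1.53, adjusted p = 0.00370), salicylate genes (median -0.32, adjusted p = 0.00991) and jasmonate genes (median -0.16, adjusted p = 0.0226) lower. Adjusted over the list alone, 5 morning clock genes and 1 heat shock gene were lower, and 0 members of the other 5 lists passed. With an estimated correlation the 7 lists had an adjusted p of 0.480 to 0.853. The morning clock did not pass without the 5 libraries (median -0.0453, adjusted p = 0.125), nor the jasmonate genes with the covariate (adjusted p = 0.0594).

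Genotypes at 2 h were compared for the level of each transcript in drying leaves. Of the mutated genes only GRF6 was called. The edgeR test called 4 genes, all lower in grf6 grf8, with 512 genes at an unadjusted p under 0.05 where chance gives 942.1, and DESeq2 called 19. Leaving out the 5 libraries with high cell cycle scores gave 9 genes, with 1094 at an unadjusted p under 0.05, and the score as a covariate gave 7, with 1058. With all 24 libraries and no covariate, the genes besides GRF6 were AT4G08170 (log2 fold change -1.14, SE 0.163, adjusted p = 0.00360), AT2G30740 (-0.87, SE 0.132, adjusted p = 0.00702) and, named after its values were seen, MSTRG.13239 (-6.71, SE 0.571, adjusted p = 8.9e-07). For AT4G08170, grf6 grf8 against WT at 2 h was not called without grf6 grf8 2 h replicate 3 (adjusted p = 0.0545) or in a fit of the 2 h groups alone (0.101), in a range of 1.7e-07 to 0.101 over its alternatives. For AT2G30740, grf6 grf8 against WT at 2 h was not called without grf6 grf8 2 h replicate 2 (0.0539) or replicate 3 (0.0545), nor in a fit of the 2 h groups alone (0.102), in a range of 5.65e-07 to 0.102 over its alternatives. That fit called 5 genes, of which 2 were among the 4. Without replicate 3 the comparison called 2 genes, and another grouping of the same libraries called 164, so chance is not excluded for this count. Camera passed 16 lists. The 14-3-3 family passed as higher with 1 member lower, and 7 higher and 2 lower adjusted over the list alone (median 0.37, adjusted p = 0.000170), the evening clock as higher, 2 higher adjusted over the list alone (median 0.31, adjusted p = 8.58e-07), and the morning clock as lower, 2 lower adjusted over the list alone (median -0.26, adjusted p = 0.000289). The ABF/ABI factors were higher, 1 adjusted over the list alone (median 0.32, adjusted p = 0.00144). Raffinose synthesis was lower, 1 adjusted over the list alone (median -0.35, adjusted p = 0.0272), and the drought factors were higher, 1 adjusted over the list alone (median 0.16, adjusted p = 0.0310).

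The other 10 of these lists at 2 h had no member called over all genes or adjusted over the list alone. Effectors (median 0.12, adjusted p = 0.0263), photosynthesis (median 0.13, adjusted p = 0.00865) and floral organ genes (median 0.74, adjusted p = 0.0263) were higher in grf6 grf8. Wax (median -0.28, adjusted p = 0.0263), nitrate (median -0.58, adjusted p = 0.00509), jasmonate (median -0.30, adjusted p = 0.000473), expansin (median -0.89, adjusted p = 0.0272), Aux/IAA (median -0.32, adjusted p = 0.0263), flavonoid (median -1.69, adjusted p = 6.58e-05) and glucosinolate genes (median -0.40, adjusted p = 0.000326) were lower. With an estimated correlation the adjusted p of the 16 lists was 0.261 to 0.803. Without the 5 libraries with high cell cycle scores 4 of the 16 lists did not pass. These were the effectors (median -0.0662, adjusted p = 0.774), drought factors (-0.0489, 0.930) and expansins (0.0565, 0.842), whose medians turned direction, and the Aux/IAA genes (adjusted p = 0.560). With the score as a covariate the drought factors (0.0650) and raffinose synthesis (0.0543) did not pass.

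Genotypes at 4 h were compared for the last time point. No ABA or drought gene was called in the edgeR test. That test called 3 genes, 1 higher and 2 lower in grf6 grf8, with 731 at an unadjusted p under 0.05 where chance gives 942.1, and DESeq2 called 16. The score as a covariate gave 25 genes, 10 higher and 15 lower, with 2117 at an unadjusted p under 0.05, and leaving out the 5 libraries with high scores gave 3, all lower, with 846. With all 24 libraries and no covariate, the genes besides GRF6 were MSTRG.13239, named after its values were seen (log2 fold change -7.27, SE 0.637, adjusted p = 1.52e-06), and AT2G16365, which was higher (0.76, SE 0.116, adjusted p = 0.0112). For AT2G16365, grf6 grf8 against WT at 4 h was not called without WT 4 h replicate 3 (adjusted p = 0.0975) or grf6 grf8 4 h replicate 1 (0.0522), nor in a fit of the 4 h groups alone (1.00) or without the 5 libraries (0.223), in a range of 1.04e-06 to 1.00 over its alternatives. Without WT 4 h replicate 4 the comparison called 6 genes, and another grouping of the same libraries called 6365, so chance is not excluded for this count. That grouping put WT 4 h replicate 4 and grf6 grf8 4 h replicates 1 and 2, which have high scores, on the same side. Camera passed 10 lists without a called member. Evening clock genes (median 0.38, adjusted p = 8.74e-06, 2 higher adjusted over the list alone), cell cycle genes (median 0.59, adjusted p = 0.0294), floral organ genes (median 1.502, adjusted p = 0.0472) and flavonoid genes (median 0.26, adjusted p = 0.0477) were higher. Salicylate (median -0.59, adjusted p = 2.51e-05), Aux/IAA (median -0.49, adjusted p = 0.000206), glucosinolate (median -0.40, adjusted p = 0.000963), morning clock (median -0.25, adjusted p = 0.0172), aquaporin (median -0.27, adjusted p = 0.0236) and raffinose genes (median -0.50, adjusted p = 0.0279) were lower. Adjusted over the list alone, 0 members of the other 9 lists passed. The 10 lists had, with an estimated correlation, an adjusted p of 0.577 to 0.774. When the 5 libraries were left out, 7 of these lists did not pass: cell cycle (adjusted p = 0.840), aquaporins (0.840), flavonoid (0.938), floral organs (0.428), glucosinolate (0.349), raffinose (0.298) and Aux/IAA genes (0.0954). With the covariate 6 did not: cell cycle (0.990), flavonoid (median -0.18, adjusted p = 0.889), morning clock (0.422), aquaporins (0.285), floral organs (0.282) and raffinose (0.182).

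The differences of the response between genotypes asked directly whether genes responded otherwise in the mutant. No ABA, wax or drought gene was called in either test, and the gene that the edgeR test called lies 0.793 Mb from GRF6. In the simulated counts these tests recovered 13.4% (2 h) and 25.4% (4 h) of genes changed 2-fold. Differences of that size or smaller can therefore go uncalled. At 2 h and at 4 h the edgeR test called 1 gene, AT5G07810, which is named after its values were seen, with 467 and 449 genes at an unadjusted p under 0.05 where chance gives 942.1, and DESeq2 called 5 and 3. With the cell cycle score as a covariate 2 genes were called at 2 h and 1 at 4 h, and without the 5 libraries with high scores 1 and 2. The second gene at 2 h with the covariate was GRF8 (1.254, adjusted p = 0.0156), which did not pass without the 5 libraries (0.147). AT5G07810 (chromosome 5, 2491200 to 2498542) had a response higher in grf6 grf8 by 3.14 (SE 0.347, adjusted p = 0.000189) at 2 h and by 3.06 (SE 0.343, adjusted p = 0.000235) at 4 h. In grf6 grf8 it rose from 0.333 CPM at 0 h to 1.12 and 2.01 CPM. In WT it fell from 3.44 CPM to 1.295 CPM at 2 h (log2 fold change -1.40, SE 0.234, adjusted p = 6.48e-05), and 2.44 CPM at 4 h did not pass against 0 h (adjusted p = 0.0779). The gene was not tested with the stricter filter, which called 0 genes at both times. The 4 h test called 2 genes without WT 0 h replicate 4, grf6 grf8 0 h replicate 4 or grf6 grf8 4 h replicate 4. Camera passed 8 lists at 2 h and 10 at 4 h, none with a member called. The aquaporins had the smallest adjusted p at both times, responding less in grf6 grf8 at 2 h (median -0.40, adjusted p = 6.74e-06) and at 4 h (median -0.64, adjusted p = 1.51e-10). With an estimated correlation the adjusted p of the lists was 0.433 to 0.910 at 2 h and 0.155 to 0.956 at 4 h. Of the 8 and 10 lists, 5 and 4 still passed without the 5 libraries, and 8 and 7 with the covariate.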

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

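The tests without the 5 libraries with high cell cycle scores and with the score as a covariate were chosen after the result was seen, and the score joined the values tested after the data had been examined for structure. One library of a group was set against the other 3 by Dixon's test, and of 96 sets of 4 values 4 had such a library, where chance alone marks about 1 in 20, or 4.8. WT 2 h replicate 3 had 5.14% of its counts in the 10 top genes, against 6.86% to 7.12% in the others. WT 4 h replicate 4 had 0.0140% of its counts in organelle genes, against 0.0236% to 0.0244%. The cell cycle score of grf6 grf8 0 h replicate 1 was 1.28, against 0.102 to 0.209. GRF6 in grf6 grf8 4 h replicate 4 was 63.9 CPM, against 43.7 to 44.8 CPM.

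Next come the gene and lists that passed the test of the difference of response, where chance is not excluded for their numbers. For AT5G07810 the response in grf6 grf8 minus that in WT was 3.14 at 2 h and 3.06 at 4 h, with a rise in grf6 grf8 from a low level at 0 h and a fall in WT at 2 h. At 2 h the median differences of the lists passed by camera were -0.40 for aquaporins, -0.53 for nitrate assimilation, 0.16 for photosynthesis, -0.76 for ethylene biosynthesis, -0.61 for brassinosteroid biosynthesis, -0.50 for Aux/IAA genes, -2.94 for flavonoid synthesis and -0.68 for glucosinolate synthesis. At 4 h they were -0.38 for PP2C phosphatases, -0.64 for aquaporins, 0.0878 for photosynthesis, -0.80 for ethylene biosynthesis, 0.23 for the evening clock, 1.83 for heat shock proteins, -0.68 for Aux/IAA genes, 0.31 for flavonoid synthesis, -0.57 for glucosinolate synthesis and 0.93 for floral organ markers. No member was called, and no list passed with an estimated correlation. Without the 5 libraries with high cell cycle scores the nitrate, ethylene and Aux/IAA lists did not pass at 2 h, nor at 4 h photosynthesis, ethylene, evening clock, flavonoid, glucosinolate and floral organ genes. With the score as a covariate PP2C phosphatases, flavonoid and floral organ genes did not pass at 4 h. Adjusted over the list alone, 1 nitrate and 1 brassinosteroid gene at 2 h and 3 heat shock genes at 4 h passed.

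The deposited FPKM were used only for checks. In grf6 grf8 2 h replicate 2, 17 genes had a count of 0 with an FPKM above 0, the most of any library, against 5 in the library with the fewest.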

How the results depend on the processing

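The tests without the 5 libraries and with the cell cycle score as a covariate were chosen after the result was seen. Over the named genes, 10677 values from alternatives were compared with their main values: 10231 kept call and direction, 398 were weaker, 30 stronger and 18 turned direction. The replicate numbers gave little sign of pairing libraries. Across 60 pairs with the same number the median correlation of deviations was 0.0439 (-0.783 to 0.628), and 21 pairs lay over 0.1. With different numbers the median was -0.00305, and 6 of 24 libraries correlated best with their own number. The fit with the number as a block kept all counts within 1.5 times. Except for the 2-fold minimum, which can only lower a count, the cause of the changes was not tested.

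With a 2-fold minimum, counts were 4318, 5332 and 410 in WT (2 h against 0 h, 4 h against 0 h, 4 h against 2 h) and 4531, 5518 and 1045 in grf6 grf8. In a fit of only the groups compared, 4 h against 2 h gave 37 genes in WT and 1312 in grf6 grf8, and the difference of the 2 h response gave 2. DESeq2 called 1647 genes in WT at 4 h against 2 h, 14, 19 and 16 between genotypes at 0 h, 2 h and 4 h, and 5 and 3 for the differences of the 2 h and 4 h response. RLE size factors gave 2 genes for the difference of the 4 h response. The stricter filter gave 5 genes between genotypes at 4 h and 0 and 0 for the differences of response.

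Leaving out the 5 libraries with high cell cycle scores gave 4010 genes in WT and 5861 in grf6 grf8 at 4 h against 2 h, 12 and 9 between genotypes at 0 h and 2 h, and 2 for the difference of the 4 h response. With the score as a covariate these were 3854 and 6099 at 4 h against 2 h, 8, 7 and 25 between genotypes at 0 h, 2 h and 4 h, and 2 for the difference of the 2 h response. The size of the response in grf6 grf8 relative to WT was -0.00576 at 2 h with genes changed at least 4-fold, and without the 5 libraries -0.0701 at 2 h and 0.150 at 4 h.

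With an estimated correlation 0 lists passed in each of the 11 comparisons. With fry, 20, 19 and 2 lists passed in WT at 2 h, 4 h and 4 h against 2 h, 16, 21 and 0 in grf6 grf8, and 0 in the genotype comparisons and differences of response. fry tests whether a list moves on balance and does not compare it with other genes. Camera without the 5 libraries passed 4 lists in grf6 grf8 at 4 h against 2 h, 5 between genotypes at 4 h and 4 for the difference of the 4 h response, and with the covariate 4 in grf6 grf8 at 4 h against 2 h.

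Directions turned for a few genes near no change or driven by one library. For GRF8, grf6 grf8 2 h against 0 h gave -0.0213 with the stricter filter, -0.0133 without the 5 libraries and -0.00987 with the covariate. Without the 5 libraries SEP2, WT 2 h against 0 h, was -0.713, and PDF1, WT 4 h against 0 h, and PYK10, WT 4 h against 0 h, were -0.726 and -0.00447.

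Leaving out 1 library at a time, the ranges were 388 to 3455 genes in WT at 4 h against 2 h, 1318 to 2055 in grf6 grf8 at 4 h against 2 h, 2 to 4 between genotypes at 2 h, 2 to 6 at 4 h, and 1 to 2 for the difference of the 4 h response. The size of the response ranged from -0.102 to 0.118 at 2 h and from -0.0974 to 0.111 at 4 h. The log2 fold change ranged from -0.686 to 4.14 for SEP2, WT 2 h against 0 h. It ranged from -0.756 to 8.73 for PDF1, WT 4 h against 0 h, from -0.0204 to 4.90 for PYK10, WT 4 h against 0 h, and from -0.0552 to 0.121 for GRF1, WT 4 h against 0 h. It ranged from -0.0522 to 0.141 for GRF1, grf6 grf8 4 h against 0 h, from -0.0107 to 0.0802 for GRF8, grf6 grf8 2 h against 0 h, and from -0.152 to 0.182 for GRF11, grf6 grf8 against WT at 0 h.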

Other observations

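All tests of genotype averaged over the 3 times, the tests of resistance and clock genes, the test of linkage without the covariate and the splits without GRF6 and GRF8 were chosen after the comparisons had been seen. Averaged over times, the edgeR test called 16 genes between genotypes, 5 higher and 11 lower in grf6 grf8, with 827 at an unadjusted p under 0.05 where chance gives 942.1, and with the cell cycle score as a covariate it called 52, with 2222 at an unadjusted p under 0.05. Genes named here were chosen after their values were seen. MRD1 (AT1G53480, log2 fold change -4.21, SE 0.621, adjusted p = 0.00237) and HEI10 (AT1G53490, log2 fold change -1.59, SE 0.289, adjusted p = 0.0317), which overlap on chromosome 1, were lower in grf6 grf8. So were 2 genes of intracellular resistance receptors, AT1G63350 (log2 fold change -0.50, SE 0.0845, adjusted p = 0.0161) and AT5G46490 (log2 fold change -0.45, SE 0.0835, adjusted p = 0.0409). Over 98 genes of such receptors the mean log2 CPM was lower by 0.216 (two-sided exact p = 0.00120 over 343000 exchanges of genotype labels within times, adjusted p = 0.00371 over 7 tests). The 98 genes include these 2 and were chosen after the comparisons had been seen, so the test gives no independent support.

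Evening-phased clock genes were higher in grf6 grf8 by a mean of 0.382 (two-sided exact p = 0.00159, adjusted p = 0.00371) and morning-phased ones lower, with a mean of -0.264 (exact p = 0.00964, adjusted p = 0.0169). Both lists had passed camera between genotypes in the same libraries at some times, so these tests give no independent support. With the covariate ELF4 (AT2G40080, log2 fold change 0.99, SE 0.138, adjusted p = 0.00118) and COR27 (AT5G42900, log2 fold change 1.01, SE 0.158, adjusted p = 0.00512) were called as higher. In the same test neither aquaporins (mean difference 0.0976, exact p = 0.424) nor salicylate genes (-0.317, exact p = 0.339) passed. Camera had passed aquaporins as higher at 0 h and lower at 4 h, and a mean over times can cancel such differences. The harvest hour of each plant is not in the labels.

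In the 5 libraries with a cell cycle score over 1, the tests of genotype and of thinning were chosen after the result was seen. Younger dividing tissue in the sample is a possible explanation: deviations of 157 ribosomal protein genes from their group mean followed the score over 24 libraries (rho = 0.910, r = 0.908, permutation p = 1e-05 for each, the smallest the permutations can give, adjusted p = 4e-05 over 4 relations, r = 0.878 without the 2 farthest). Depth was left open by its relation to the score (rho = -0.354, p = 0.0910, adjusted p = 0.121, and r = -0.362, p = 0.0814, adjusted p = 0.0814, r = -0.369 without the 2 farthest), but after thinning all libraries to the lowest total the 5 scores still lay 0.523 above the other 19. Photosynthesis genes were related to the score inversely by r (r = -0.568, permutation adjusted p = 0.00898, r = -0.307 without the 2 farthest), but rho did not pass (rho = -0.452, adjusted p = 0.0559). The share of the 10 top genes had no relation that passed (rho = -0.230, adjusted p = 0.278, and r = -0.379, adjusted p = 0.0814). The score averaged 0.366 in WT and 0.565 in grf6 grf8 (two-sided exact p = 0.567), which leaves a difference between genotypes open. At 4 h its means were 0.514 in WT and 1.07 in grf6 grf8. How the leaves were picked is not stated in the labels.

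The other 9 members of the 14-3-3 family were higher in grf6 grf8 in 26 of 27 combinations of member and time, with a median log2 difference of 0.338. Reads assigned to one member but coming from another were left open. Younger tissue could not account for it alone, since the median was 0.352 with the cell cycle score as a covariate and 0.293 without the 5 libraries. Scaling was unlikely, since the members lay at percentile 100 of 10000 random lists matched on expression and 26 combinations were higher with RLE size factors too. An effect of genotype had an exact p of 4.08e-05 (two-sided, adjusted p = 0.000286 over 7 tests), and GRF5 (log2 fold change 0.60, SE 0.0696, adjusted p = 8.32e-05) and GRF9 (log2 fold change 0.65, SE 0.0923, adjusted p = 0.00171) were called over the 3 times. The exact test and these calls use the same libraries that showed the pattern, so they give no independent support.

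Sequence linked to the 2 mutated loci, both on chromosome 5, was tested as a source of genotype calls. Among genes called over the 3 times with the cell cycle score as a covariate, GRF6 and GRF8 left out, 3 of 49 with a position lay within 2 Mb of either locus (6.12%), against 8.09% of the other genes (two-sided Fisher's exact p = 0.796). Without the covariate it was 2 of 13 (15.4%), against 8.08% (two-sided Fisher's exact p = 0.284). Near GRF6 these were AT5G07810 at 0.793 Mb and GRF5 at 1.96 Mb, called in both fits. Near GRF8 it was MAF5 (AT5G65080) at 0.151 Mb, called only with the covariate. MSTRG.13239 has no position. Linkage was left open by the small number of calls.

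Each group comparison was repeated on the 35 ways to divide its 8 libraries into 4 and 4. Chance was excluded for the number of genes in WT at 2 h (7963, highest other 722, 1 split as large, the real one) and 4 h (9425, highest other 3159, 1 split), and in grf6 grf8 at 2 h (8203, highest other 0, 1 split), 4 h (9645, highest other 461, 1 split) and 4 h against 2 h (2286, highest other 0, 1 split). Since GRF6 and GRF8 part the genotypes by design, the genotype splits were counted without them too. At 0 h the real split alone called the most, with all genes (5, highest other 2) and without GRF6 and GRF8 (3, highest other 2). Its share of the splits, 0.0286, is the smallest that 35 splits can give and was not adjusted over comparisons. With counts so close, this is weak evidence against chance. Without GRF6 and GRF8, chance was not excluded at 2 h (3, highest other 164, 2 splits) or 4 h (2, highest other 6363, 6 splits). For the number of all genes it was not excluded in WT at 4 h against 2 h (884, highest other 5592, 3 splits as large), nor between genotypes at 2 h (4, highest other 164, 2 splits) and 4 h (3, highest other 6365, 6 splits). Between genotypes at 4 h, every other split that called genes put WT replicate 4 and grf6 grf8 replicates 1 and 2 together. These libraries had cell cycle scores over 1, and the splits called 2856 to 6365 genes. In WT at 4 h against 2 h, the splits with 5592 and 2010 genes kept replicates 4 of both times together, also over 1. Other splits that did so called as few as 0. These patterns were seen after the result, and why other splits call many genes was not tested.

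For the number of lists passed by camera the splits excluded chance nowhere. Some splits keep most libraries of a group together and so hold part of the real difference. Others divide both groups evenly and hold none of it, yet camera passed lists in them too. Between genotypes at 0 h such even splits passed 4 to 13 lists, against 7 in the real grouping. In WT at 4 h against 2 h they passed 1 to 16, against 6. In grf6 grf8 at 4 h against 0 h their highest was 9, against 14. Passing camera at the preset correlation is therefore not, by itself, evidence of a difference between groups. In WT at 2 h 10 lists passed and 15 of 35 splits passed as many (highest other 15), at 4 h 10 (11 splits, highest other 14) and at 4 h against 2 h 6 (23 splits, highest other 16). In grf6 grf8 these were 11 (13 splits, highest other 15), 14 (3 splits, highest other 15) and 7 (13 splits, highest other 12). Between genotypes they were 7 at 0 h (20 splits, highest other 15), 16 at 2 h (2 splits, highest other 17) and 10 at 4 h (8 splits, highest other 12). For the differences of response, 100 arrangements of the labels were used, the real one among them. As many as the 1 gene called were found in 6 at 2 h (highest other 2) and 12 at 4 h (highest other 3861), and as many as the 8 and 10 lists in 52 (highest other 16) and 26 (highest other 15).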
